A study of Mus musculus with 2 samples.

How the data were processed

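Genomic DNA of Paneth cells sorted by fluorescence from the small intestine of reporter mice was sequenced directly on nanopores, per the labels' protocols. There was 1 library from germ-free and 1 from specific-pathogen-free mice, grouped by their titles, which also name the ileum. How many mice gave each library, their sex and the sequencing depth were not given in the sources used here. The base caller, the modification caller, the aligner and the region caller were also not given in the sources used here. The build was mm10, per the submitters' processing notes.

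The analysis started from 2 tables that the authors deposited, one for 5mC and one for 5hmC, each with 1 line per region and overlapping gene feature. Per the file headers, each line holds the region's position and number of CpGs, its mean level in group 1 and in group 2 as a fraction from 0 to 1, the difference of those fractions, and a summed statistic. The statistic is a score with no fixed range, computed by the authors. A positive deposited difference means that group 1 is higher. The difference equalled the group 1 level minus the group 2 level in every line, to within 1e-06 percentage points. The sign of the statistic was opposite to that of the difference in 12 5mC regions and 1 5hmC region, and direction was taken from the difference. The deposited tables hold only regions the authors called and annotated to a gene, without p-values or read counts. How the threshold was set, and how regions were filtered, was not given in the sources used here, and regions below it were not analysed here. Because depth is unknown, no interval was given for any level.

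Levels were multiplied by 100 and given as percent. The 51246 5mC and 742 5hmC lines were collapsed to 31743 and 478 distinct regions by chromosome, start and end. A region with several annotations was put in promoter, 5′ UTR, exon, 3′ UTR, intron or 1 to 5 kb upstream, in that order. Since a 3′ UTR lies within exons, no region fell to the 3′ UTR class, although 2948 5mC regions touched one. Group 1 and group 2 were kept as the tables name them, and results planned as higher in SPF were computed as higher in group 2.

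With 1 library per group no test between the groups was possible, and no p-value was computed. Shares carry exact Clopper-Pearson intervals at 95%, and medians carry order-statistic intervals. These cover counting error over regions, which are not replicates. CpG-dense meant at least 10 CpGs per 100 bp, and partly methylated meant a mean level of 20 to 60% over both groups. Both limits were set after seeing the data. CpG counts were used as deposited, and whether a CpG was counted once or on each strand was not given. The region at Samd1 held 167 counted CpGs in 385 bp, close to the most that its length allows. Counts and densities of CpGs may therefore be too high, and the density limits hold for these counts only.

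Gene identifiers of the tables were matched to a RefSeq gene table of assembly GRCm38, the assembly behind mm10: 8228 of 8234 identifiers for 5mC and 413 of 413 for 5hmC. Before the data were examined, 17 gene lists of 569 symbols were fixed, of which 567 symbols matched the reference by symbol or by a synonym of 1 gene. Unmatched symbols were left out, and where several symbols led to the same gene it was counted once. The 45 symbols of the Paneth cell list thus gave 40 genes and the 30 of the DNA methylation machinery list 29. The lists were Paneth cell and antimicrobial genes, secretory lineage regulators, Wnt, Notch and niche genes, microbial sensing, interferon and MHC, autophagy and ER stress, DNA methylation machinery, nutrient and bile acid genes, circadian, imprinted, and Hox and developmental genes, and markers of goblet, enterocyte, enteroendocrine and tuft, stem and progenitor, immune and stromal cells. Some genes stand on 2 lists, as Lyz2, Xbp1 and Apob do. For each list the share of regions higher in group 2 was ranked among 10000 random lists of listed genes matched on regions per gene, and the number of members with a region among 10000 random lists of coding genes matched on length. These percentiles describe the 2 libraries.

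The rule for named genes was also fixed before the data were examined. Per modification and direction, it took the 6 genes with the largest absolute region statistic, 1 region per gene, leaving out provisional and small RNA symbols. From each list it took up to 4 members with the largest statistic per modification, and all 5mC regions at promoters of the Paneth cell list. Genes with overlapping 5mC and 5hmC regions would have been added, but there were none. Some genes that the rule selects are not reported here.

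Overlap of 5hmC with 5mC regions needed at least 1 bp and was counted with bedtools 2.31.1, and set beside 1000 random placements. The other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The list ranking was tested on simulated data made on the 8234 genes of the 5mC comparison. Among 200 simulated lists of 12 genes with 30% of regions higher in group 2, 100% ranked above the central 95% of random lists. Of 200 lists with no planted difference, 2.50% fell outside it. These simulations drew each region independently, so regions of a gene did not move together and level had no effect. Their planted share also lay above that of every real 5mC list, the highest being 20%. The overlap count equalled an all-pairs count in 20 of 20 simulations.

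Alternatives planned before the data were examined were regions that differ by at least 30 percentage points, regions of at least 10 CpGs, the upper part of the regions split at the median statistic, regions off the sex chromosomes, annotation entries in place of regions, weights by region length, other overlap rules, and promoter regions alone. Alternatives chosen after seeing the data were the median difference of a list, random regions matched on mean level in classes of 10 percentage points, the 5mC regions without the CpG-dense partly methylated class, and placement near genes.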

Results

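DNA of Paneth cells, the granule-bearing secretory cells at the base of small intestinal crypts, was read directly on nanopores in 2 libraries. One library came from germ-free (GF) mice, which carry no microbes, and 1 from specific-pathogen-free (SPF) mice, which carry a microbiota free of listed pathogens. The cells had been sorted by fluorescence from the small intestine of reporter mice, and the library titles name the ileum. The question was how colonisation relates to 5-methylcytosine (5mC) and 5-hydroxymethylcytosine (5hmC), the oxidised form of 5mC, in these cells. Every region, level and difference given here comes from the authors' deposited table for that modification, which lists only regions that they called different between the 2 groups. Those tables name their groups 1 and 2. GF stands before SPF in the name of the comparison, so group 1 was likely GF and group 2 likely SPF, but no header or label states it, and the groups are therefore called by number. There were no replicates, so no difference could be set against a spread between animals, and sequencing depth was unknown. Coordinates are on the mouse build mm10.

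In the authors' deposited table for 5mC, nearly every listed region was lower in group 2. Regions upstream of Lyz2, across the antimicrobial lectin gene Reg3g and at an annotated promoter and intron of the inflammasome gene Nlrc4 followed this direction. Lyz2, the macrophage lysozyme gene, stands on both the Paneth cell and the immune list. Levels at Lyz2, Reg3g and Nlrc4 were 65.3%, 82.2% and 74.9% in group 1 against 45.7%, 46.9% and 26.4% in group 2. Of 31743 distinct regions, 30737 (96.8%) were higher in group 1 and 1006 (3.17%, exact binomial interval 2.98 to 3.37%) were higher in group 2. The minority included CpG-dense promoters of low level, such as that of the H3.3 histone gene H3f3a, and promoters of the X chromosome, such as that of the chromatin cofactor gene Hcfc1.

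The median level of a 5mC region was 79.5% in group 1 (quartiles 72.0 and 83.4%) and 57.0% in group 2 (quartiles 44.8 and 64.9%). The median absolute difference was 20.3 percentage points (interval of the median 20.2 to 20.4, quartiles 15.5 and 26.6). Regions higher in group 1 differed by a median of 20.5 points and regions higher in group 2 by 11.8 points. A region had a median length of 161 bp and a median deposited count of 8 CpGs, and all regions together covered 8.12 Mb and 8234 genes. These intervals cover counting error over regions only. The share higher in group 2 was 0.888% among regions that differed by at least 30 points and 5.87% among regions of at least 10 CpGs.

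**Figure D1:**
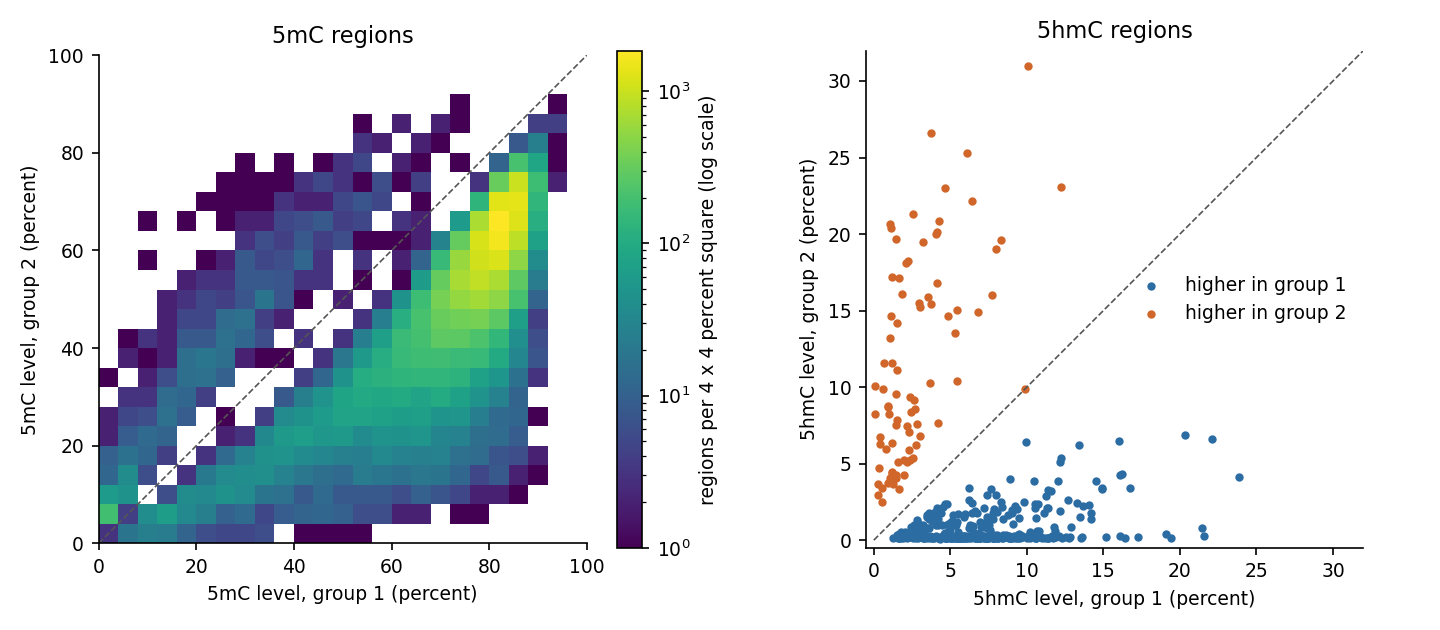
Levels of each listed region in group 1 (horizontal axis, percent) and group 2 (vertical axis, percent), from the authors' deposited tables. The left panel counts 31743 5mC regions per square on a log colour scale, the right panel shows 478 5hmC regions as points, and the dashed line marks equal levels. Most regions of both modifications lie below the line.

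Genes with the largest statistics among 5mC regions lower in group 2 in the authors' deposited table included a myosin chaperone gene and an X-linked gene of respiratory complex I. The region with the largest deposited CpG count, 542, lay in an intron and upstream of Unc45b, a myosin chaperone gene (chromosome 11, 82930061 to 82931900). It stood at 13.3% in group 1 and 6.90% in group 2. A region 1 to 5 kb upstream of Mamdc4, which encodes an apical endosomal glycoprotein (chromosome 2, 25576345 to 25579113), stood at 57.5% and 35.3%. The promoter and 5′ end of the transcription factor gene Tcfl5 (chromosome 2, 180641746 to 180642949) stood at 29.4% and 16.8%. One X-linked region at the promoters of Ndufa1, a gene of respiratory complex I, and its neighbour Rnf113a1 (X, 37190445 to 37191981) stood at 39.1% and 11.9%. An intron of the neuropeptide S receptor gene Npsr1 (chromosome 9, 24147354 to 24149260) stood at 86.2% and 54.1%.

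Regions of the X chromosome, histone genes and a zinc finger gene had the largest statistics in the opposite direction in the authors' deposited table. They do not stand for their families, which were picked after the data were seen. Of 37 regions of clustered histone genes 7 were higher in group 2, and of 690 regions of Zfp zinc finger genes 19 were. A region over the promoter and exons of Cited1, a transcriptional coregulator gene (X, 102249904 to 102253015), was at 34.0% in group 1 and 49.5% in group 2. The promoter of Hcfc1 (X, 73964463 to 73967985) was at 23.1% and 48.5%. An exon reaching into the 3′ UTR of the zinc finger gene Zfp316 (chromosome 5, 143253068 to 143254294) was at 53.8% and 70.4%. One region upstream of the H2B histone genes H2bc23 and H2bc24 (chromosome 13, 21812759 to 21814836) was at 7.54% and 29.3%. The promoter of H3f3a (chromosome 1, 180812976 to 180814355) was at 2.37% and 7.14%.

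Paneth cell and antimicrobial genes carried 32 5mC regions in the authors' deposited table, at 13 of 40 matched genes, and 30 of these regions were lower in group 2. At enteric alpha-defensin genes, which encode the main granule peptides of Paneth cells, a region over Defa3 exons and introns (chromosome 8, 21287716 to 21289432) stood at 56.8% in group 1 and 29.3% in group 2. A region upstream of the uroguanylin gene Guca2b (chromosome 4, 119663512 to 119664366) stood at 76.2% and 43.5%. The 3 promoter regions of this group were also lower in group 2. These lay at Clps, a colipase gene (35.1% and 14.9%), Ttr, the transthyretin gene (63.1% and 34.0%), and Defa38 (48.7% and 22.8%). The 2 regions that ran the other way lay in an exon and intron of Ttr (14.8% and 34.0%) and in an intron of the lipase gene Pnliprp2 (56.4% and 68.2%), and were named after their values were seen. The share of regions higher in group 2 lay at percentile 73.4 among 10000 random gene lists matched on regions per gene, a description of these 2 libraries.

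**Figure D2:**
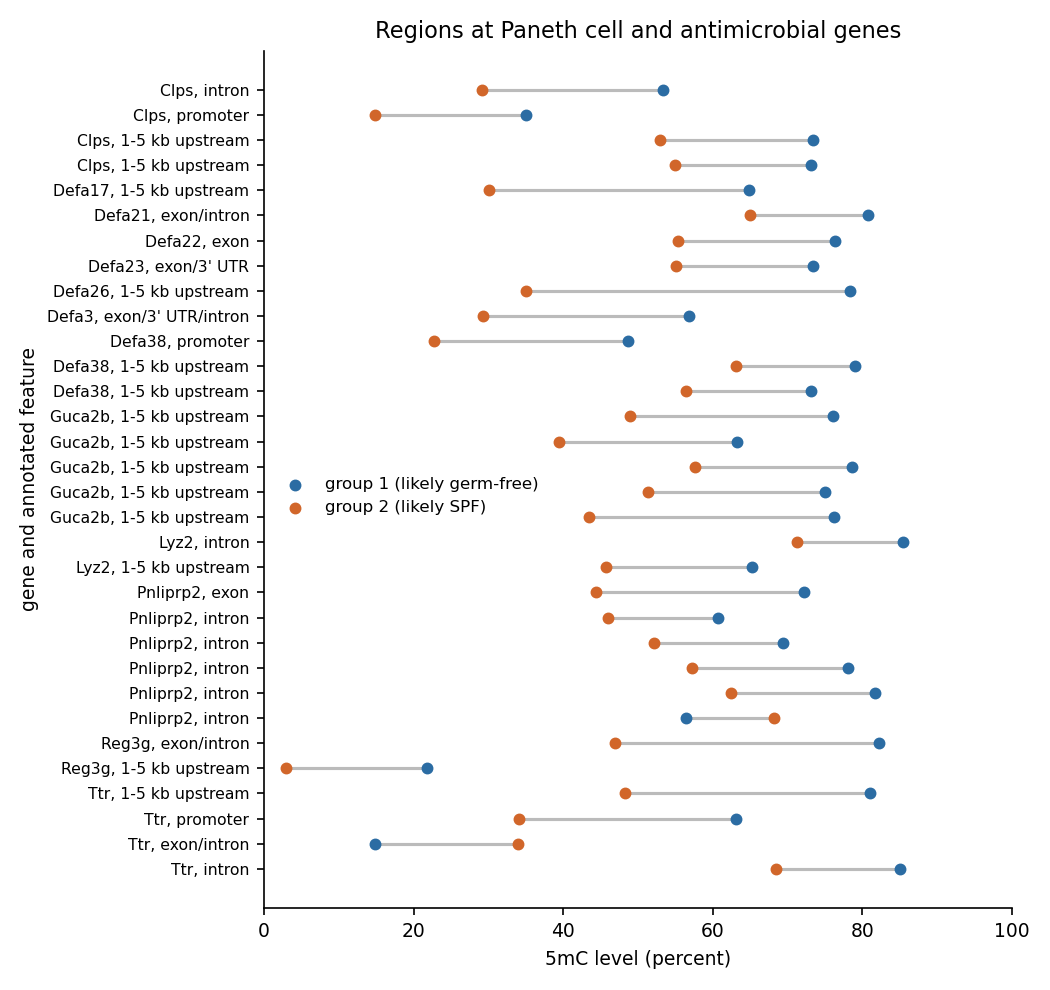
5mC level (percent) of the 32 listed regions at 13 Paneth cell and antimicrobial genes, from the authors' deposited table, with 1 line per region joining group 1 (blue) and group 2 (orange). In 30 regions the group 2 level is the lower one, and the exceptions lie in Pnliprp2 and Ttr.

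Genes of microbial recognition and of interferon and antigen presentation ran the same way in the authors' deposited table. All 49 regions at 11 of 47 microbial sensing genes were lower in group 2. They included a region annotated to both a promoter and an intron of Nlrc4 (chromosome 17, 74453831 to 74454743). Another lay in an exon and 3′ UTR of Tlr9, the receptor for unmethylated CpG DNA (21.5% and 11.95%). An intron of the inflammasome gene Nlrp1b stood at 85.1% and 52.5%, and a region upstream of the adaptor gene Card9 at 83.8% and 55.3%. Of 47 regions at 17 of 48 interferon and MHC genes, 45 were lower in group 2. A region annotated to a promoter, exon and intron of Irf9, a transducer of interferon signals (chromosome 14, 55605843 to 55606486), stood at 84.0% and 46.4%. Regions in the MHC class II gene H2-Aa (66.0% and 25.9%), in B2m (63.7% and 38.5%) and upstream of Irf7 (70.9% and 52.9%) ran the same way. The shares higher in group 2 lay at percentiles 10.9 and 57.6 of matched random lists.

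Secretory lineage, niche and stress genes showed the same majority in the authors' deposited table. Of 25 regions at 5 of 33 secretory lineage regulators, 23 were lower in group 2, among them regions of Xbp1, a master factor of the secretory stress response (55.9% and 31.5%), the Notch effector Hes5 (24.3% and 10.4%), Erbb3 (75.2% and 61.4%) and the intestinal homeobox gene Cdx1 (6.03% and 2.56%). Of 33 regions at 8 of 42 Wnt, Notch and niche genes, 30 were lower in group 2, with introns of the Notch ligand gene Jag1 at 62.2% and 32.8%, of Ereg at 52.1% and 32.0% and of Wnt6 at 57.6% and 30.1%, and a region upstream of Fzd2 at 63.9% and 31.5%. Of 49 regions at 12 of 44 autophagy and ER stress genes, 47 were lower in group 2. Regions of Atg12, a gene of the autophagy conjugation system (58.2% and 33.9%), and of Ern2, an ER stress sensor gene of secretory epithelium (22.2% and 12.1%), were among them, while the promoter of the chaperone gene Dnajb9 was higher in group 2 (2.45% and 6.16%).

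All 49 regions at 5 of 29 matched genes of the DNA methylation machinery were lower in group 2 in the authors' deposited table. A region at the maintenance methyltransferase gene Dnmt1, annotated to a promoter, exon and intron, stood at 83.8% and 62.3%. A region at the glycosylase gene Tdg, also annotated to a promoter, exon and intron, stood at 86.8% and 57.7%. The promoter region of the glycosylase gene Mbd4 stood at 49.995% and 29.1%, and a region of Dnmt3l at 79.3% and 46.6%. Nutrient and bile acid genes had 36 regions at 7 of 37 genes, 33 of them lower in group 2, including introns of the sugar transporter gene Slc2a2 (52.0% and 33.4%), the ileal bile acid transporter gene Slc10a2 (79.3% and 47.7%) and Cd36 (84.1% and 73.7%). A region of the apolipoprotein gene Apob was higher in group 2 (3.86% and 18.5%). Circadian genes had 8 regions at 2 of 19 genes, 7 of them lower in group 2, with regions upstream of Dbp at 66.5% and 38.7% and of Bhlhe41 at 83.1% and 66.9%.

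Imprinted genes showed the same majority in the authors' deposited table, and a smaller majority stood at Hox and developmental genes. Of 62 regions at 10 of 43 imprinted genes, 59 were lower in group 2, and the share higher in group 2 lay at percentile 76.3 of matched random lists. A region upstream of H19, a maternally expressed noncoding RNA gene (chromosome 7, 142579873 to 142581454), stood at 57.7% and 33.6%, a region of Dlk1 at 62.5% and 45.9% and an intron of Cmklr2 at 83.7% and 61.3%, while the promoter of Mcts2 (chromosome 2, 152686554 to 152687756) stood at 41.0% and 59.2%. Hox and developmental genes had 49 regions at 17 of 52 genes, of which 8 (16.3%) were higher in group 2. Their share lay at percentile 99.2 of random lists matched on regions per gene, and their median difference of 12.2 points at percentile 0, but those lists were not matched on level, and the median levels here were low (33.3% and 26.7%). Among 10000 sets of random regions matched on mean level, an alternative chosen after seeing the data, the side turned: the median share was 28.6% (central 95% 20.4 to 38.8%), and 16.3% lay at percentile 0.46. Those sets drew single regions and so ignored that regions of 1 gene may move together. Regions of Lhx1 (46.4% and 31.6%) and Hoxa7 (33.3% and 16.4%), and 1 region assigned to both Hoxa11 and Hoxa10 (9.94% and 5.61%), were lower in group 2. Hox and developmental genes were the only one of 17 lists outside the central 95% by share in either comparison, where 0.85 lists would fall by chance. With promoter regions alone 4 of 6 such regions (66.7%) ran higher in group 2, and with differences of at least 30 points none of 3 did.

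Markers of other cells that a sort of intestinal tissue could hold were measured beside these groups in the authors' deposited table. Enteroendocrine and tuft cell markers had 34 regions at 16 of 28 genes, against a median of 10 genes in random lists matched on gene length (percentile 99.3), and 32 regions were lower in group 2. All 17 lists were ranked by number of genes in this way, and their percentiles ran from 1.10 to 99.3. By chance 0.85 lists would fall outside the central 95%. Regions of Trpm5, the tuft cell channel gene (57.8% and 34.5%), and Cck (52.2% and 26.3%) were lower in group 2, and regions of Pyy (4.82% and 10.4%) and Isl1 (26.7% and 57.8%) were higher. Goblet markers had 17 regions at 5 of 16 genes, 16 of them lower in group 2, with Agr2 at 56.2% and 20.4%, Tpsg1 at 60.1% and 41.1%, Ccl6 at 71.5% and 49.5%, and the trefoil gene Tff3 in the other direction at 4.92% and 12.4%. Enterocyte markers had 10 regions at 2 of 23 genes, among them Apob, against a matched median of 7 genes (percentile 1.10), and 8 regions were lower in group 2. No gene was listed for both modifications, so this count may be tied to the 5hmC count of the same list.

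Stem and progenitor markers had 11 regions at 2 of 20 genes, all lower in group 2, with Cdca7 at 61.4% and 38.8% and the telomerase gene Tert at 81.9% and 57.4% in the authors' deposited table. Immune markers had 57 regions at 12 of 35 genes, of which 53 were lower in group 2, with Cd8a at 73.7% and 49.8% and the macrophage gene Adgre1 at 86.6% and 69.6%. The T cell factor gene Gata3 was the other way round at 43.7% and 59.7%. Stromal markers had 58 regions at 9 of 27 genes, of which 57 were lower in group 2, with Acta2 at 69.5% and 42.9%, Des at 69.4% and 43.8% and Pdgfrb at 38.5% and 21.97%, while the vimentin gene Vim stood at 3.13% and 8.18%.

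Promoters held a small part of the 5mC regions and a larger part of those higher in group 2. Promoters took 3999 regions (12.6%, exact binomial interval 12.23 to 12.97%), 5′ UTRs 506, exons 8903, introns 13029 and the stretch 1 to 5 kb upstream 5306, each region counted once in that order of priority. Of promoter regions, 9.73% (8.83 to 10.7%) were higher in group 2, and of 5′ UTR regions 9.09% (6.73 to 11.9%), against 2.09% of exon, 1.86% of intron and 2.70% of upstream regions. Promoters thus made up 38.7% of the regions higher in group 2 and 11.7% of those higher in group 1 in the authors' deposited table. Counted by annotation entry, so that a region stood once per overlapping feature, promoters made up 8.01%.

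Direction followed the level and CpG density of a 5mC region. On the autosomes, 338 of 478 regions with a mean level of at most 10% were higher in group 2 (70.7%, 66.4 to 74.8%), with medians of 3.52% in group 1 and 6.05% in group 2. The regions of H3f3a, Dnajb9, Vim and Pyy, all higher in group 2, belong to this class. So do those of Cdx1 and of Hoxa11 and Hoxa10, which were lower in group 2. The share was 27.7% at mean levels of 10 to 20%, 10.3% at 30 to 40%, 2.25% at 50 to 60% and 0.108% at 70 to 80%. By density, 148 of 255 regions with at least 20 CpGs per 100 bp were higher in group 2 (58.0%), against 1.54% of 2600 regions with under 2. Median levels were 5.53% in group 1 and 7.14% in group 2 in the densest class, against 77.8% and 45.4% in the sparsest. These shares therefore do not separate density from level.

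**Figure D3:**
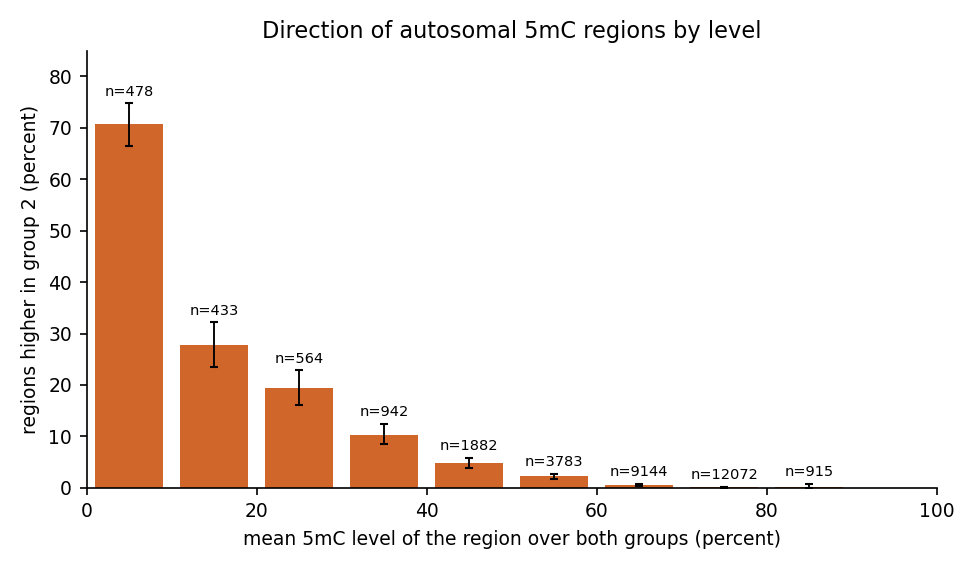
Share of autosomal 5mC regions higher in group 2 (percent, vertical axis) by the mean level of the region over both groups (percent, horizontal axis), from the authors' deposited table. Bars carry exact binomial 95% intervals for counting error over n regions, and the share is 70.7% in the lowest class and 0.108% at 70 to 80%.

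The X chromosome stood apart from the autosomes. It held 1494 5mC regions (4.71% of all, interval 4.48 to 4.95%), of which 97 were higher in group 2 (6.49%, 5.30 to 7.86%), against 906 of 30213 on the autosomes (2.999%), where single chromosomes ranged from 1.56 to 4.80%. The promoter regions of Cited1 and Ndufa1 belong to a class of X promoters of high CpG density and intermediate level, as genes subject to X inactivation have in female cells. Of 72 such promoter regions on X, 45 were higher in group 2 (62.5%, 50.3 to 73.6%) and 27 higher in group 1, with median levels of 32.6% and 34.9%. Of 119 such regions on the autosomes, 24 were higher in group 2 (20.2%, 13.4 to 28.5%), with median levels of 50.1% and 38.6%. Levels thus differed between X and the autosomes within this class, and the shares were not matched on level. Among all other X regions, 33 of 1378 were higher in group 2 (2.39%). The share of 5mC regions on X was 7.96% among those that differed by at least 30 points. The tables also listed 9 5mC and 3 5hmC regions on the Y chromosome, the latter at Zfy1 and Rbmyf7, which were named after their values were seen. The sex of the mice was not given in the sources used here.

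**Figure D4:**
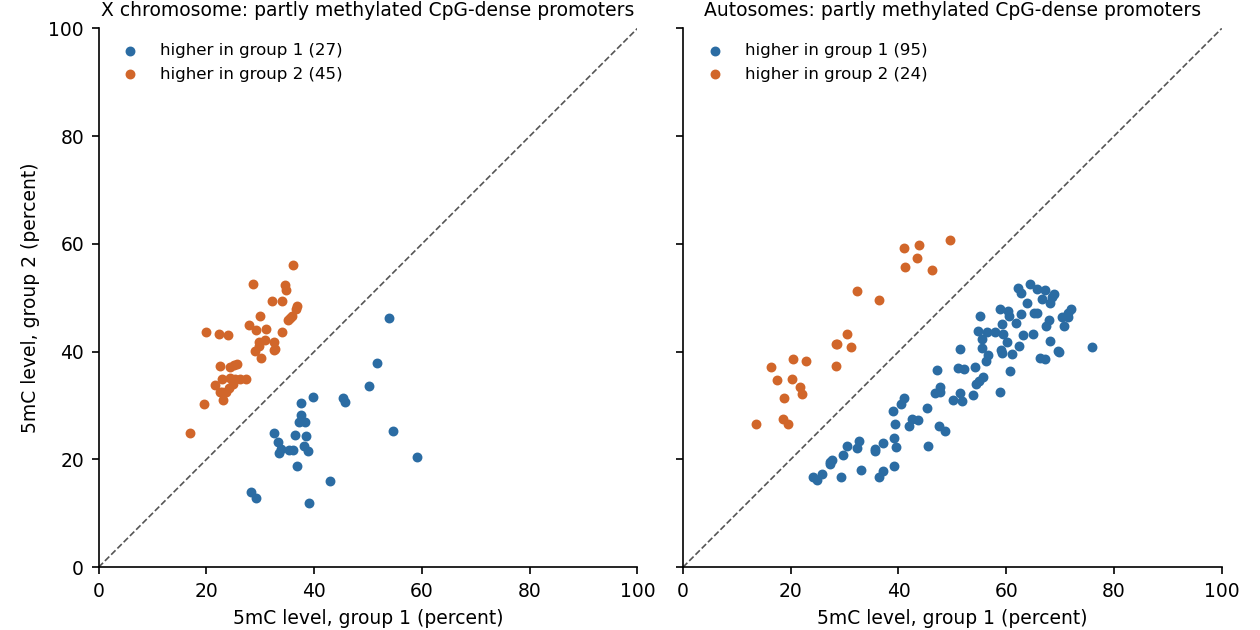
5mC level in group 1 (horizontal axis, percent) and group 2 (vertical axis, percent) of partly methylated CpG-dense promoter regions, 72 on the X chromosome (left) and 119 on the autosomes (right), from the authors' deposited table. On X, 45 points lie above the line of equal levels and 27 below it, against 24 and 95 on the autosomes.

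For 5hmC the authors' deposited table listed far fewer regions, and most were lower in group 2. The enterocyte genes Alpi, Apoa4 and Apoc3 and the Hox genes Hoxd8, Hoxc13, Hoxb7 and Hoxa13 carried regions that were all higher in group 1, while regions of the ribosomal protein gene Rpl37a and the replication clamp gene Pcna were higher in group 2. Of 478 regions at 413 genes, 393 (82.2%) were higher in group 1 and 85 (17.8%, exact binomial interval 14.5 to 21.5%) were higher in group 2. The median level was 5.58% in group 1 and 0.388% in group 2, and the median absolute difference was 6.02 percentage points (5.53 to 6.47). Group 2 levels were often near 0, with quartiles of 0.185 and 2.27%. Some distant regions held identical group 2 levels, such as 0.300856% at chromosome 6 positions 6568278 and 142755383. Levels this near 0 may thus not be separate measurements, and their depth is unknown. The largest difference was 22.8 points. On the autosomes, 5.48% of 73 regions with a mean level up to 2% were higher in group 2, against 71.4% of 28 regions above 10% (51.3 to 86.8%). Mean level was bound to the size of the difference, with medians of 6.25% and 19.2% in that top class. The shares therefore do not separate level from size of difference.

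Promoters took 101 5hmC regions (21.1%, 17.6 to 25.1%), exons 114, introns 94, the stretch 1 to 5 kb upstream 158 and 5′ UTRs 11. Of the promoter regions, 23.8% (15.9 to 33.3%) were higher in group 2, against 18.2% of 5′ UTR, 17.7% of upstream, 17.02% of intron and 13.2% of exon regions (7.56 to 20.8% for exons), and these intervals overlap. Among 459 regions off the sex chromosomes the share was 17.6%.

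Among genes with the largest 5hmC statistics in the authors' deposited table, levels were low in both groups. An exon and 3′ UTR of Hnrnpa0, which encodes an RNA-binding protein (chromosome 13, 58127341 to 58127984), stood at 5.19% in group 1 and 1.68% in group 2. Promoter regions of Nudt10 (X, 6172625 to 6173184), Samd1 (chromosome 8, 83997945 to 83998329) and the mitochondrial ribosome gene Mrps26 (chromosome 2, 130563591 to 130564313) stood at 6.23%, 9.96% and 2.67% in group 1 against 3.38%, 6.40% and 0.744% in group 2. The 5′ UTR and exon of Hoxd8 (chromosome 2, 74705228 to 74705546) stood at 3.97% and 1.85%, and an exon of the neurogenic factor gene Neurog2 (chromosome 3, 127633733 to 127634173) at 2.07% and 0.515%.

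Higher in group 2 were the promoters of Rpl37a (chromosome 1, 72710977 to 72711626), at 1.07% and 4.07%, of the Notch pathway gene Hes6 (chromosome 1, 91412946 to 91413557), at 1.31% and 4.28%, and of the translation factor gene Eef1b2 (chromosome 1, 63176547 to 63176811), at 1.21% and 3.87%, in the authors' deposited table. Regions of Ubfd1 (chromosome 7, 122067467 to 122067872), the homeobox gene Uncx (chromosome 5, 139543901 to 139544184) and Mab21l1 (chromosome 3, 55780284 to 55780565) stood at 2.59%, 4.18% and 2.73% in group 1 against 5.35%, 7.66% and 6.20% in group 2.

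By gene list, 7 of 17 lists had any 5hmC region in the authors' deposited table. Enterocyte markers led them: 4 of 23 genes had a region, where random lists matched on gene length had a median of 0 (percentile 99.99), and all 5 regions were higher in group 1. That percentile ranks the number of genes and not the direction, and 82.2% of all 5hmC regions were higher in group 1. The share of enterocyte regions higher in group 2 lay at percentile 14.9 of random lists matched on regions per gene. An exon and intron of the brush border phosphatase gene Alpi (chromosome 1, 87100480 to 87100830) stood at 8.77% and 1.62%, and 1 region shared by the apolipoprotein genes Apoa4 and Apoc3 (chromosome 9, 46238925 to 46239231) at 6.84% and 0.426%. Because Apoa4 and Apoc3 share that region, the 4 genes are not independent. No gene was listed for both modifications, so the 5hmC and 5mC counts of a list may not be separate results. For 5mC, 2 of 23 enterocyte markers had a region (percentile 1.10). No gene of the Paneth cell and antimicrobial list had a 5hmC region, where matched lists had a median of 1. Outside that list, Defa28 and Defa32, named after their values were seen, carried 1 5hmC region each, both higher in group 1 (medians 13.1% and 0.191%). They were 2 of 71 defensin genes, a family picked after the data were seen, and random lists matched on gene length also had a median of 2.

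Hox and developmental genes had 7 5hmC regions at 4 of 52 genes (matched median 1, percentile 97.9), all higher in group 1 in the authors' deposited table. Their share higher in group 2 lay at percentile 14.975 of random lists matched on regions per gene. Exons of Hoxc13 and Hoxa13 stood at 6.21% and 2.65% and at 4.07% and 0.976%, and the promoter of Hoxb7 at 2.19% and 0.110%. The other 5 lists had 1 gene each. Regions of Ticam1, an adaptor gene of Toll-like receptors (20.3% and 6.89%), Isg15, an interferon-induced gene (2.43% and 0.839%), the enteroendocrine factor gene Insm1 (2.90% and 1.13%) and the glial gene Sox10 (4.99% and 0.201%) were higher in group 1, and a region upstream of Pcna was higher in group 2 (3.75% and 15.4%). The secretory lineage, niche, autophagy, DNA methylation machinery, nutrient, circadian, imprinted, goblet and immune lists had 0 regions.

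No 5hmC region overlapped a 5mC region, and no gene stood in both of the authors' deposited tables. Lyz2, Reg3g and Nlrc4 stood in the 5mC table alone, and Alpi, Rpl37a and Hnrnpa0 in the 5hmC table alone. Of 478 5hmC regions, 0 shared a base with a 5mC region, against a mean of 2.64 (range 0 to 8) when the 5hmC regions were placed at random on their chromosomes 1000 times, with 0 in 79 placements. With placement within 5 kb of genes, an alternative chosen after seeing the data, the mean was 5.54 (range 0 to 15), with 0 in 2 placements. The nearest pair lay 1571 bp apart. Among 21896 protein-coding genes of the reference, 6496 had a 5mC region and 296 a 5hmC region, so that independent lists would share 87.8 genes, and 0 were shared.

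Long genes were rarely listed for 5mC. A region was listed at 44.4% of 2451 coding genes of 2 to 5 kb (42.5 to 46.4%), at 18.1% of those of 30 to 100 kb, at 5.61% of 1872 of 100 to 300 kb (4.61 to 6.75%) and at 7 of 556 above 300 kb (1.26%, 0.508 to 2.58%). For 5hmC the share was 3.14% at 2 to 5 kb and 0 above 100 kb. A gene that is not in these tables is therefore not shown to be equal between the groups.

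**Figure D5:**
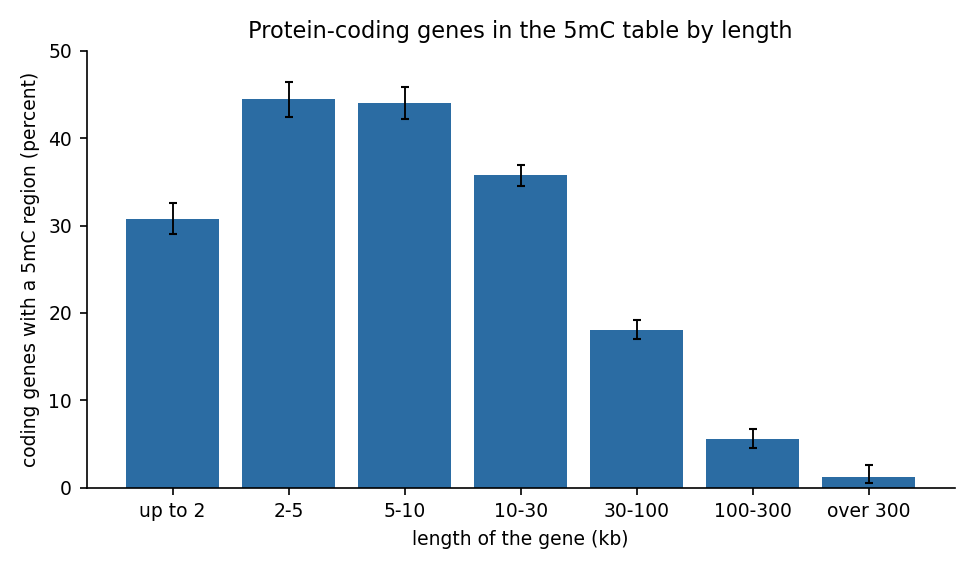
Share of protein-coding genes with a listed 5mC region (percent, vertical axis) by the length of the gene (kb, horizontal axis), from the authors' deposited table and the reference gene annotation. Bars carry exact binomial 95% intervals for counting error over genes, and the share is 44.4% at 2 to 5 kb and 1.26% above 300 kb.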

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

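Direction held under every alternative for the share of regions higher in group 2 of both modifications, which stayed below 50%, but sizes moved. The alternatives without the CpG-dense partly methylated class, with the median difference of a list, with random regions matched on level and with placement near genes were chosen after seeing the data. Causes were not tested unless named. Depth is unknown, so a coverage minimum could not be varied. No paired analysis was possible because each group has 1 library.

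For 5mC, the share higher in group 2 was 0.888% among regions differing by at least 30 points, 5.87% with at least 10 CpGs, 4.69% in the upper part by statistic, 4.36% over annotation entries, 4.24% weighted by length and 2.80% without the CpG-dense partly methylated class. In the same order up to length weighting, the median absolute difference was 35.4 (raised by the limit itself), 19.6, 21.1, 19.9 and 23.7 points, and the share at promoters was 9.09, 16.9, 15.2, 8.01 and 15.6%. Off the sex chromosomes the promoter share was 12.2%. The share on X was 7.96% at 30 points or more and 6.67% weighted by length.

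For 5hmC no region differed by 30 points, so that alternative gave no value. With at least 10 CpGs, in the upper part by statistic and over annotation entries, the median absolute difference was 4.33, 4.37 and 5.50 points and the share at promoters 28.0, 27.6 and 14.02%. Overlapping regions stayed at 0 within 1000 bp, the only overlap rule that could have raised the count, since the stricter rules can only lower it. The number of lists outside the central 95% of their random lists was 1 in the planned setting, with the median difference and with matching on level (the Hox and developmental list, then on the low side), 0 at 30 points or more, 1 with promoter regions and 2 off the sex chromosomes. With promoter regions alone the majority turned to group 2 in the Hox and developmental list (66.7% of 6 regions), the Wnt, Notch and niche list (100% of 1 region) and the enterocyte list (100% of 1 region). Of 46 list values, 24 stayed within their interval, 19 moved and 3 turned. Secretory, circadian and stem lists at 30 points, and secretory and circadian lists at promoters, had no region left.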

Other observations

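Several gene families that stand in clusters were listed for 5mC more often than coding genes of like length, in families picked after the data were seen. Keratin-associated protein genes, which encode hair matrix proteins, had a region at 35 of 56 members in the authors' deposited table, against 16 in the median matched list (central 95% 10 to 23), and keratin genes at 35 of 53, against 23 (16 to 30). Vomeronasal receptor genes, which serve pheromone sensing, had a region at 145 of 355 members against 106 (90 to 123), Zfp zinc finger genes at 173 of 397 against 130 (113 to 148), and clustered histone genes at 30 of 67 against 19 (12 to 26). Olfactory receptor genes went the other way, with 316 of 1110 against 351 (327 to 375). In vomeronasal genes 4 of 384 regions were higher in group 2, with median levels of 77.5% and 49.3%, and in clustered histone genes 7 of 37 were. Neighbouring genes of a cluster can share a region, so members are not independent.

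Ribosomal protein genes, a family also picked after the data were seen, among them Rpl37a, were listed for 5hmC at 7 of 77 members, against 2 in the median matched list (central 95% 0 to 6), and for 5mC at 31, against 32. Of their 10 5hmC regions, 3 were higher in group 2, with median levels of 4.21% and 0.683%.

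All tests in the following paragraphs were chosen after the results they address were seen, and a biological difference between germ-free and colonised mice stays open for each pattern as untested.

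The 5mC level was lower in group 2 in nearly all listed regions. One proportional fall of all levels in that library would lower low regions too, and 70.7% of listed autosomal regions with a mean level of at most 10% were higher in group 2, but a fall from a low level could be too small to be called. More wrong calls at both ends of the scale could raise low regions and lower high ones, and the median drop was 19.1 points where group 1 stood at 80 to 90% and 24.2 points at 50 to 60%. Only 5 of 31743 regions differed by under 1 point, so the calling shapes both values, and neither explanation can be told apart from a change in the cells. Levels at sites that were not called different, with their depth, would be needed.

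Partly methylated CpG-dense promoters of the X chromosome differed in both directions. A different share of female cells would move them one way, yet only 62.5% ran the more frequent way (upper bound 73.6%, counting regions as independent). This split argues against such a share as the whole cause. It cannot speak against the share combined with a general fall, since 97.6% of the other X regions were lower in group 2. A candidate explanation is that few long reads sampled the methylated and unmethylated X unequally from place to place. Of 12 pairs of these promoter regions within 20 kb, 83.3% ran the same way, which equals the upper end of the central 95% (25 to 83.3%) when directions were shuffled over them, so the pairs are too few to decide; over all 116 X regions of this density and level, promoters or not, 75.7% of 37 pairs did, against 35.1 to 67.6%. Pairs can be parts of 1 CpG island, and a local change in the cells would give the same value, while regions listed on Y, 9 for 5mC and 3 for 5hmC, leave male cells in either library open.

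The tables share no gene. A filter that acted on single regions would list long genes at least as often as short ones, but 1.26% of coding genes above 300 kb were listed for 5mC against 44.4% at 2 to 5 kb. A filter that kept only genes with regions of 1 modification may account for both facts, since long genes would more often carry both kinds, and genes of 100 to 300 kb were listed at 5.61%. Filters on other properties that grow with gene length were not tested. Under such a filter the absence of overlap would be set by how the tables were made.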
